A study of Homo sapiens with 6 samples.

How the data were processed

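RNA from 6 samples of COLO320 cells was sequenced, 3 with an ALDH1A1 hairpin and 3 with a scramble hairpin, with library preparation by a TruSeq RNA kit per the labels' protocols. The authors deposited 1 table of FPKM values, fragments per kilobase of transcript scaled for library size, with 1 column per sample. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2, Cufflinks and Cuffdiff were used. Those notes name hg19, GRCh38 and hg38 without saying which served for what, and the annotation and settings are not given in the sources used here. The labels' extraction text speaks of retina, which does not match a cell line. The table had 23615 rows. The value 0.0001 was its lowest and appeared to have been added to every value, since all 4438 values of 100 FPKM or more ended in 1 at decimal place 4. Such a row is described as listed at 0. Symbols of 28 rows had been turned into dates, 2 of them on 2 rows each. These rows were kept and are not named. With no counts, no count model was used, and the absolute depth is unknown.

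Groups came from the labels, where the control samples are called wild type and their titles mark them as scramble. Titles of the knockdown samples hold the letters KO, although a hairpin is described. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (moderated test with a mean trend, 4 residual and 2.98 prior degrees of freedom) for the 12211 rows with a mean of at least 1 FPKM, with Benjamini-Hochberg adjustment and a threshold of 0.05. The pseudocount of 1 understates changes of low genes. Folds are ratios of mean FPKM. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 23 lists with at least 5 measured members out of 26. Estimated correlations and fry, which tests whether the genes of a set move without comparing them with other genes, were alternatives. ALDH1A1 was also tested with an exact permutation test over 20 splits. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. By that rule ALDH1A1, the 12 largest rises and 12 largest falls with an adjusted p under 0.05, a gene symbol and groups that do not overlap are named, leaving out clone, small RNA and pseudogene rows, and up to 4 members per list. The text gives values mostly for members whose call held whichever library was left out.

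Alternatives were other pseudocounts, filters, scalings, variance models, sample weights, thresholds and each library left out. Quantile normalization, among the scalings, gives every sample the same distribution, so it can remove a real shift of the highest genes. Alternatives chosen after seeing the data were a per-sample loess correction for transcript length and GC (span 0.5), small RNA and date rows left out, and ALDH1A1 left out of its list. Lengths, GC and positions came from GENCODE release 44 lifted to GRCh37, which may not be the build the authors used. It matched 10956 of 12211 tested rows by symbol or older symbol (89.7%). On simulated data with the spread of these genes (12211 genes, 3 against 3 samples), 47.8% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 97% of those changed 4-fold were called, with 7 calls among 12011 unchanged genes. In a simulated set test, both lowered lists and 0 others were called. These simulations drew each gene independently, whereas genes of a list moved together in the data (estimated correlation 0.644 for the cholesterol list). They therefore do not show how often genes or lists are called falsely when genes are correlated. The gene simulation left 12011 of 12211 genes unchanged, whereas 32.4% of rows were called in the data, so its shares may not hold there. A simulated length trend (rho 0.9 across genes) fell to -0.01 after the correction. In the data the Spearman rho of the log2 difference across genes was only 0.14 with transcript length and 0.07 with GC. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for tables and figures. Between any pair of samples 0.483% to 0.614% of rows held the same value, tested because a library can be deposited more than once.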

Results

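Gene expression was measured by RNA sequencing in COLO320 cells, an established human colon cancer line. The 6 samples fall into 2 groups of 3. In the first group a lentiviral short hairpin RNA lowered ALDH1A1, an enzyme that oxidises retinaldehyde and other aldehydes, and the second carried a scramble hairpin. The series asks what ALDH1A1 does in lipid metabolism in these cells. Each sample has 1 FPKM value per gene, and the total number of fragments per sample is unknown. The summed FPKM was 544247, 563295 and 562792 in knockdown samples 1, 5 and 6, and 656797, 641998 and 642621 in control samples 2, 3 and 6. Low values put 1 fragment at between 1 and 1.186 times its worth in knockdown sample 1, so the samples differed little in relative depth after the authors' scaling. The labels do not say whether the samples were separate cultures or how many transduced lines they came from. The p-values below therefore measure the spread between these samples, which may be technical, and a difference between transduced lines cannot be separated from the knockdown.

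ALDH1A1 itself lies on the minus strand of chromosome 9 at 75515587 to 75695358 (GRCh37) and is annotated as protein coding. Its level was 4.97, 4.26 and 3.76 FPKM in knockdown samples 1, 5 and 6. It was 173.5, 167.3 and 164.4 FPKM in control samples 2, 3 and 6. The means were 4.33 ± 0.608 and 168 ± 4.64 FPKM (SD, n = 3 each), so that 2.57% of the control level was left, a 38.9-fold lower value. On the log2(FPKM + 1) scale the difference was -5.00 (SE 0.10, limma adjusted p = 1e-06), and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 samples allow.

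**Figure D1:**
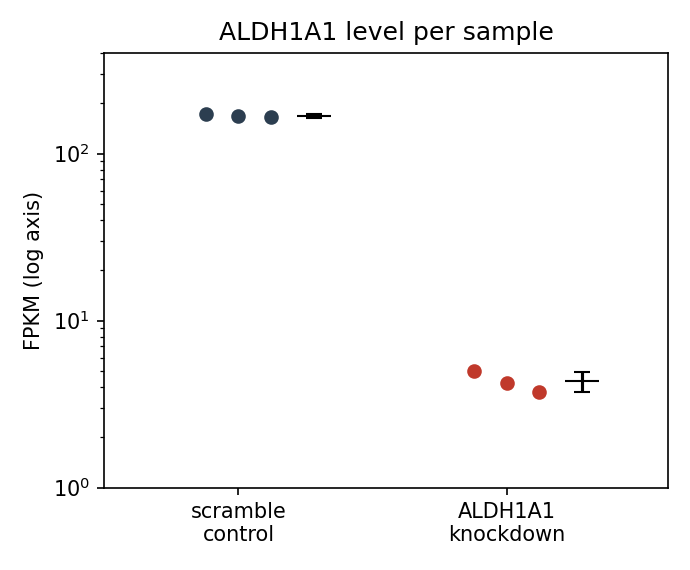
ALDH1A1 level in FPKM (vertical log axis) in each sample of the scramble control and ALDH1A1 knockdown groups, with the mean and SD of each group as a bar beside the points. The 3 control samples lie between 164.4 and 173.5 FPKM and the 3 knockdown samples between 3.76 and 4.97 FPKM.

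Many other transcripts differed. The largest falls after ALDH1A1 included the chemokine receptor CXCR4, from 126 ± 59.9 to 11 ± 7.94 FPKM, the immediate early transcription factor EGR1, from 26.2 ± 6.33 to 2.35 ± 0.286 FPKM, and the Wnt antagonist WIF1, from 29.2 ± 9.20 to 5.04 ± 1.83 FPKM (mean ± SD, n = 3, here and below). The Notch-responsive repressor HES1 fell from 7.80 ± 2.16 to 0.742 ± 0.215 FPKM, while its relative HES4 rose from 1.90 ± 0.277 to 9.25 ± 1.37 FPKM. The cancer-testis antigen CTAG2, EGFLAM, PHACTR1, the lipid phosphate phosphatase PPAP2B and the collagen COL13A1 fell with log2 differences of -2.27, -2.22, -2.12, -2.08 and -1.94. RPL21 (log2 difference -2.12) and the heat shock gene HSPA1B (-2.08) fell too, but both have near-identical copies, a set of RPL21 pseudogenes and HSPA1A, so their values are uncertain.

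The largest rises included the secreted peptide gene OSTN, from 4.78 ± 3.47 to 37.3 ± 5.49 FPKM, annexin ANXA1, from 28.6 ± 10.2 to 183 ± 11.4 FPKM, and the inflammatory caspase CASP4, from 0.455 ± 0.172 to 7.35 ± 0.925 FPKM. The natriuretic peptide receptor NPR3 rose from 1.90 ± 1.03 to 12.8 ± 0.929 FPKM. WTIP, WWC3, the long noncoding RNA LINC00152, the troponin TNNC1 and WIPF3 rose with log2 differences of 1.93, 1.77, 1.72, 1.59 and 1.55. TNFRSF12A, the TWEAK receptor, had a log2 difference of 2.18 (SE 0.56, adjusted p = 0.026). Its call ended when any library other than control sample 3 was left out, with log2 differences from 1.74 to 2.38 and adjusted p of up to 0.099. EEF1A1, a translation elongation factor that every cell uses, was listed at 0 in all 3 controls and at 3390, 3591 and 3460 FPKM in knockdown samples 1, 5 and 6, so that its value is in doubt and no fold is given.

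Of 12211 genes with a mean of at least 1 FPKM, 3952 had a limma adjusted p under 0.05 in the comparison of 3 knockdown with 3 control samples, 1874 of them higher and 2078 lower in the knockdown. Among these, 92 were higher and 191 lower by at least 2-fold on the log2(FPKM + 1) scale. The groups did not overlap in 6127 genes (50.2%), where chance gives 10%. The number of calls depended on single libraries: it was 1716 without knockdown sample 5, 2111 without knockdown sample 6 and 1877 without control sample 6. Differences also followed expression level. Genes other than ribosomal protein genes had a median log2 difference of 0.01 at means of 10 to 30 FPKM, -0.13 at 300 to 1000 FPKM and -0.42 in the 25 genes at 1000 FPKM or more.

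**Figure D2:**
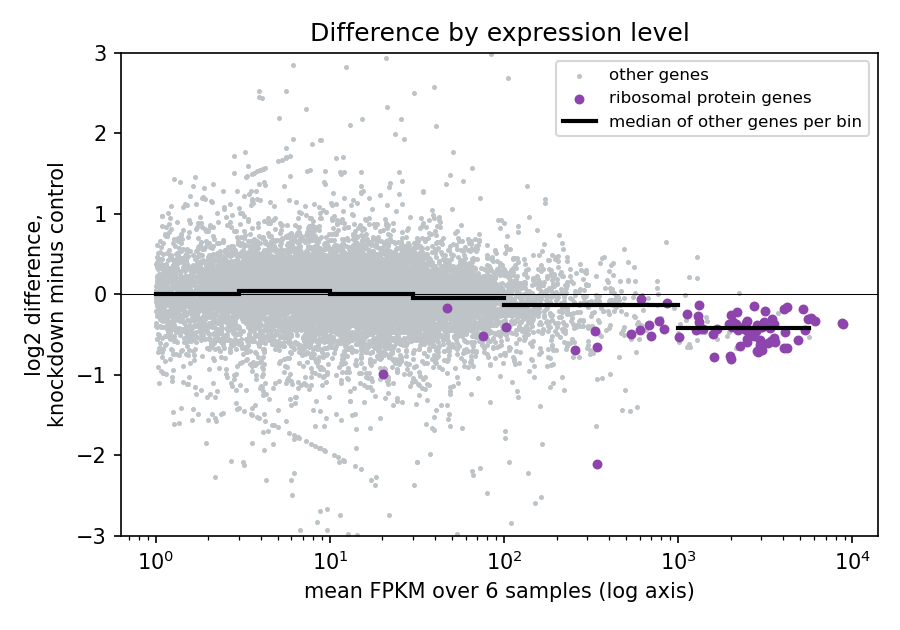
Log2 difference, knockdown minus control (vertical axis), against mean FPKM over the 6 samples (horizontal log axis) for each tested gene, with ribosomal protein genes in purple, other genes in grey and the median of the other genes per bin of mean FPKM as black lines. The medians go from 0.01 at 10 to 30 FPKM to -0.42 at 1000 FPKM or more, and 20 genes lie outside the plotted range of -3 to 3.

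Genes of cholesterol synthesis and uptake were lower in the knockdown. Of 24 measured, 15 fell and 0 rose, with a median log2 difference of -0.55. Adjusted over the list alone, 16 fell. SQLE, squalene epoxidase, fell from 47.1 ± 8.99 to 20.3 ± 2.38 FPKM. INSIG1, a sterol-regulated retention protein of the endoplasmic reticulum, went from 20.5 ± 8.37 to 6.17 ± 0.836 FPKM (log2 difference -1.50, adjusted p = 0.011), a call that ended without knockdown sample 6 (-1.44, adjusted p = 0.0505) or control sample 6 (-1.39, adjusted p = 0.0524). Other members that fell are named after their values were seen. STARD4, TM7SF2, DHCR7, FDFT1, IDI1 and NSDHL had log2 differences from -1.16 to -0.83 and stayed called whichever library was left out. HMGCS1, MSMO1, CYP51A1, EBP and SREBF2 had differences from -0.82 to -0.40. Each of these 5 lost its call without knockdown sample 5 and without control sample 6, and some without knockdown samples 1 or 6 or control sample 2, with differences no closer to 0 than -0.31 and adjusted p of up to 0.15. The list had an adjusted p of 3.9e-06 in limma's camera test with a preset correlation of 0.01, and an adjusted p of 0.8 with an estimated correlation, which was 0.644 between its genes. With fry the list's adjusted p was 0.049, just under the threshold. Without 1 library its median lay between -0.79 and -0.45. Genes matched on expression level had a median of 0.01.

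In fatty acid synthesis, elongation and desaturation, 9 of 23 measured genes fell and 2 rose (median log2 difference -0.15, which was -0.07 without control sample 2 and -0.27 without control sample 3). Adjusted over the list alone, 9 fell and 3 rose. The desaturases FADS2 and SCD fell from 28.9 ± 5.65 to 16.2 ± 1.07 FPKM and from 132 ± 20.8 to 81.3 ± 5.58 FPKM, and the elongase ELOVL2 rose from 3.75 ± 1.04 to 7.52 ± 0.863 FPKM. The list as a whole did not pass (camera adjusted p = 0.12). For fatty acid oxidation, 3 of 34 rose and 5 fell (adjusted over the list alone, 0 and 3; camera adjusted p = 0.86). For glycerolipid and phospholipid synthesis and lipid droplets, 6 of 35 rose and 6 fell (adjusted over the list alone, 7 and 6; camera adjusted p = 0.93). DGAT2, which makes triacylglycerol, fell from 9.43 ± 1.49 to 3.30 ± 0.324 FPKM, PCYT2 of phosphatidylethanolamine synthesis fell from 11.9 ± 2.56 to 5.67 ± 0.182 FPKM, and PISD rose from 10.2 ± 0.874 to 15.5 ± 0.948 FPKM. In sphingolipid metabolism 3 of 22 rose and 4 fell (adjusted over the list alone, 4 and 4; camera adjusted p = 0.93), with SGPL1, the sphingosine phosphate lyase, rising from 10.9 ± 0.972 to 20 ± 0.296 FPKM and SGPP1 falling from 11.3 ± 1.23 to 7.16 ± 0.737 FPKM. Among genes of fatty acid uptake and binding and eicosanoid enzymes 7 of 24 rose and 6 fell (adjusted over the list alone, 7 and 6; camera adjusted p = 0.93). The sphingolipid and uptake lists had medians of 0.01 and 0.02 and means of -0.01, and camera put both upward. The nuclear receptor PPARG rose from 6.47 ± 1.36 to 15.2 ± 0.25 FPKM, whereas the fatty acid transporter CD36 fell from 288 ± 55.5 to 141 ± 26.1 FPKM and ACSL4, an acyl-CoA synthetase, from 18.3 ± 0.541 to 9.95 ± 0.934 FPKM.

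**Figure D3:**
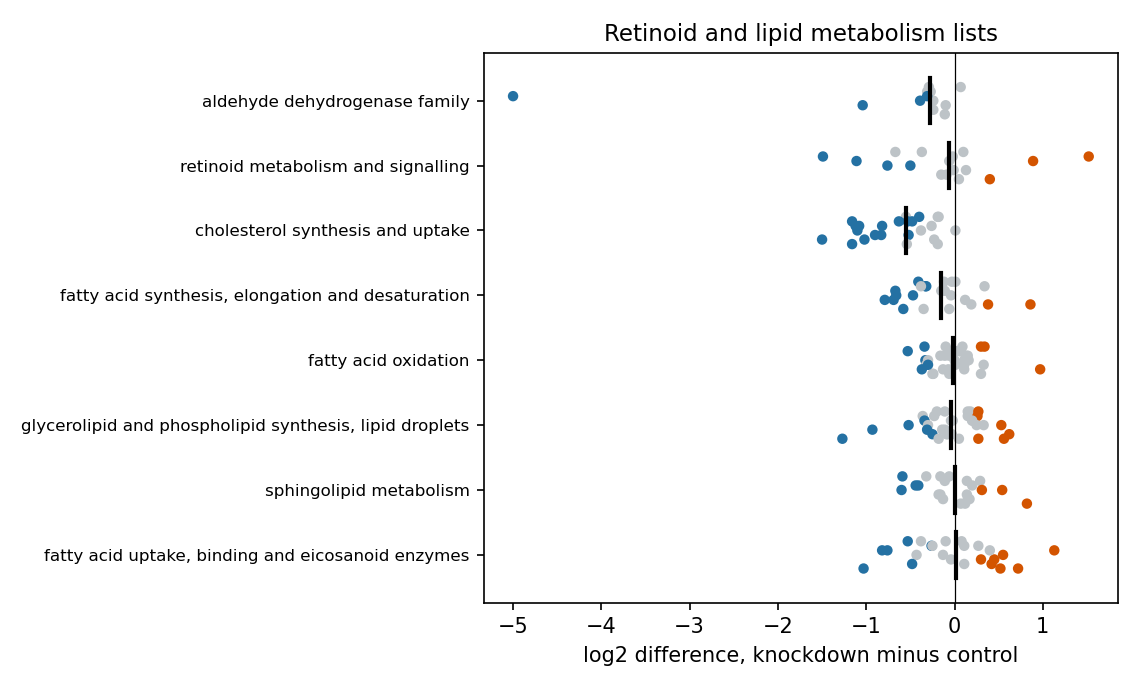
Log2 difference, knockdown minus control, of each measured gene (point) in the 8 lists of retinoid and lipid metabolism, with blue for genes that fell, orange for genes that rose, grey for those with an adjusted p of 0.05 or more, and a black bar at each median. The cholesterol list has the lowest median, -0.55, and the point at -5.00 is ALDH1A1.

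In the retinoid list 3 of 17 measured genes rose and 4 fell, and adjusted over the list alone the counts were the same (median log2 difference -0.06, camera adjusted p = 0.79). The cellular retinoic acid binding protein CRABP2 rose from 5.41 ± 0.799 to 17.4 ± 2.55 FPKM, and the retinaldehyde reductase DHRS3 fell from 30.1 ± 7.16 to 13.2 ± 1.59 FPKM. SOX9 had a log2 difference of -1.49 (adjusted p = 0.016), a call that ended without knockdown sample 5 (-1.45, adjusted p = 0.061), knockdown sample 6 (-1.46, adjusted p = 0.062) or control sample 6 (-1.42, adjusted p = 0.066). Of 12 measured aldehyde dehydrogenases 4 fell and 0 rose, also when adjusted over the list alone (median -0.28). The list's camera adjusted p of 0.011 included the targeted gene: it was 0.0546 with ALDH1A1 left out and 0.0582 with a minimum mean of 0.1 FPKM, and the adjusted p was 0.8 with an estimated correlation. Without control sample 2 the median was -0.18. ALDH1B1 had a log2 difference of -1.04 (adjusted p = 0.013), and its call ended without knockdown sample 5 (-1.01, adjusted p = 0.057) or knockdown sample 6 (-1.02, adjusted p = 0.057).

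Ribosome biogenesis and MYC-linked genes were lower, with 16 of 30 falling and 0 rising (adjusted over the list alone, 18 and 1), a median of -0.34, which was -0.20 after quantile normalization, and a camera adjusted p of 0.0032. The adjusted p was 0.8 with an estimated correlation and 0.0783 with array weights. Genes matched to the list on expression level had a median of -0.08. MYCN fell from 7.06 ± 2.06 to 2.67 ± 0.451 FPKM and PA2G4 from 192 ± 18.4 to 103 ± 4.6 FPKM. MYC, named after its values were seen, had a mean of 2630 FPKM in the controls and 1660 FPKM in the knockdown (log2 difference -0.67, SE 0.08, adjusted p = 0.0021). Its difference was -0.25 after quantile normalization, -0.68 after median-centring and -0.67 after correction for transcript length and GC. The 25 genes at 1000 FPKM or more, MYC among them and ribosomal protein genes left out, had a median of -0.42. For the nuclear-encoded respiratory chain 10 of 35 fell and 0 rose, also when adjusted over the list alone, with NDUFB5 falling from 126 ± 5.36 to 69.7 ± 8.50 FPKM. Its camera adjusted p was 0.025, but its median of -0.09 lay at the -0.10 of genes matched on level. The adjusted p was 0.8 with an estimated correlation, 0.249 after quantile normalization, 0.525 after correction for transcript length and GC, 0.0783 with array weights, 0.241 with fry, 0.0936 without knockdown sample 1 and 0.264 without control sample 2, and the median was -0.22 without control sample 3, -0.029 after quantile normalization and -0.007 after the length and GC correction. Of 21 genes of glycolysis and lactate export 5 fell and 0 rose (adjusted over the list alone, 2 fell; camera adjusted p = 0.067, and 0.0141 without knockdown sample 1, 0.00534 without control sample 3 or 0.0121 with array weights). Their median of -0.31 was -0.17 without control sample 2 and -0.13 after quantile normalization. GAPDH fell from 1530 ± 154 to 1030 ± 59.4 FPKM, a log2 difference of -0.57 that was -0.26 after quantile normalization.

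Among Wnt targets and intestinal stem cell markers 8 of 20 fell and 2 rose (adjusted over the list alone, 10 and 2; median -0.29, camera adjusted p = 0.055, and up to 0.8 over the alternatives). The list passed in 7 of 21 fits, with an adjusted p of 0.0232 without knockdown sample 1, 0.0441 without control sample 6, 0.049 and 0.046 with pseudocounts of 0.1 and 0.01, 0.0411 without a filter, 0.0216 after correction for transcript length and GC and 0.0168 with fry. TNFRSF19 fell from 18.6 ± 1.56 to 9.73 ± 2.27 FPKM, and the cyclin CCND1 rose from 5.35 ± 1.00 to 10.5 ± 1.28 FPKM. Of 7 measured neuroendocrine markers 4 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.15, and 0.0458 without a filter or 0.00168 with fry), with the synaptic protein SNAP25 falling from 22.1 ± 2.68 to 13.6 ± 1.55 FPKM. Of 8 colonic epithelial genes 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.43): CDX2, an intestinal transcription factor, fell from 1420 ± 85.5 to 900 ± 34.2 FPKM (log2 difference -0.66, and -0.42 after quantile normalization) and the cadherin CDH17 rose from 0.953 ± 0.182 to 2.43 ± 0.357 FPKM. Of 11 mesenchymal markers 3 rose and 2 fell (adjusted over the list alone, 4 and 3; camera adjusted p = 0.56, and 0.00539 with fry), with ACTA2 rising from 0.431 ± 0.143 to 2.93 ± 0.0561 FPKM and TAGLN from 1.28 ± 0.116 to 4.06 ± 1.17 FPKM.

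In the type I interferon list 7 of 15 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.23, and 0.0241 without a filter or 0.0418 with a minimum mean of 0.1 FPKM), and IRF9 rose from 5.22 ± 0.433 to 9.62 ± 1.00 FPKM. Of 30 genes of amino acid starvation and the unfolded protein response 1 rose, DDIT3, from 106 ± 17.5 to 239 ± 6.51 FPKM, and 5 fell (adjusted over the list alone, 1 and 4; camera adjusted p = 0.86). Of 18 p53 targets 2 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.35, and 0.049 with fry), with PLK2 falling from 39.8 ± 2.52 to 20.9 ± 2.92 FPKM. In the hypoxia list 1 of 19 rose and 4 fell (adjusted over the list alone, 1 and 2; camera adjusted p = 0.23, and 0.0141 without knockdown sample 1), with NDRG1 falling from 1.81 ± 0.702 to 0.393 ± 0.0234 FPKM. In the oxidative stress list 2 of 20 rose, among them OSGIN1, from 2.01 ± 0.0887 to 4.73 ± 1.07 FPKM, and 7 fell, also when adjusted over the list alone (camera adjusted p = 0.35). The list of glutathione S-transferases and cytochrome P450 genes also holds other enzymes, POR, NQO2, UGT8 and SULT1A1. Of its 18 measured genes 5 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 0.23). GSTO1 fell from 52.5 ± 6.20 to 31.4 ± 0.824 FPKM. Of 40 S and M phase genes 4 fell and 0 rose (adjusted over the list alone, 2 fell; camera adjusted p = 0.93), PCNA from 153 ± 45.3 to 69.4 ± 3.03 FPKM and MCM6 from 25.6 ± 5.91 to 12.9 ± 0.286 FPKM. That list's median was 0.04, its mean was -0.05 and camera put it downward. Of 16 replication-dependent histone genes 2 rose and 0 fell (adjusted over the list alone, 0; camera adjusted p = 0.22).

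Markers of other cells were mostly low or listed at 0. Among them, 3 leukocyte and 4 retinal markers were listed at 0 in every sample. EEF1A1 was listed at 0 in the controls too, so a listed 0 does not by itself show absence. Of 24 leukocyte markers 21 had a mean below 1 FPKM, and of the 3 measured 1 rose and 2 fell, among them CD4, from 7.29 ± 0.767 to 2.91 ± 0.203 FPKM. Of 30 retinal markers, listed because the labels' extraction text speaks of retina, 26 had a mean below 1 FPKM, and SAG and GNAT1 reached at most 0.025 and 0.033 FPKM. Of the 4 measured, 1 rose and 2 fell, with GNB1, a broadly expressed G protein subunit, rising from 153 ± 1.18 to 206 ± 7.13 FPKM. Adjusted over the list alone, both counts were unchanged, and neither list was large enough for a set test. Mitochondrially encoded transcripts had 0 members in the table used here.

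The samples separated by group. Pearson correlations of log2 values across the tested genes, which are not independent replicates, were 0.965 to 0.970 within the knockdown, 0.956 to 0.969 within the control and 0.933 to 0.954 between groups. The first principal component held 44.7% of the variance and separated the groups. Control sample 3 lay nearest the knockdown on it, at -16.2 against -32.1 and -29.7 for control samples 2 and 6. Without control sample 3 there were 4945 calls.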

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

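Correction for transcript length and GC, leaving out small RNA and date rows, and leaving ALDH1A1 out of its list were chosen after seeing the data, and the other settings before. ALDH1A1 kept its direction and call in all 17 alternatives run on it, with log2 differences from -5.288 to -4.915. The count of 3952 genes became 10005 (5048 higher, 4957 lower) with array weights, whose estimate stopped before converging and gave knockdown sample 5 a weight of 33.1. It became 1532 (662 and 870) at an adjusted p under 0.01 and 283 (92 and 191) with at least a 2-fold difference, where fewer genes can pass by construction. Leaving out 1 library gave 1716 to 4945 genes, 736 to 2401 of them higher and 980 to 2544 lower, with 1716 without knockdown sample 5, 2111 without knockdown sample 6 and 1877 without control sample 6. The other settings gave 3088 to 4377. No gene called both as reported and in an alternative with its own list of calls changed sign. Lists called rose from 4 to 7 without a filter on low values and with fry, and fell to 0 with an estimated correlation, with 3 to 6 in the other settings. Except where said, the cause was not tested.

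Lists that did not pass as reported turned direction in the test under some settings, none with a call. Medians of glycerolipid and phospholipid genes were -0.038 without a filter, -0.036 at a mean of 0.1 FPKM, -0.062 at 5 FPKM, and -0.08 to -0.024 without 1 library. Those of sphingolipid genes were -0.014 without a filter, -0.039 at 0.1 FPKM, and -0.051 to 0.027 without 1 library. Fatty acid uptake genes had -0.017 without a filter, -0.071 at 0.1 FPKM, -0.042 at 5 FPKM, 0.037 after quantile normalization, 0.018 with fry, and -0.023 to 0.05 without 1 library. S and M phase genes had 0.108 after quantile normalization, 0.057 after length and GC correction, and -0.121 to 0.206 without 1 library. Mesenchymal markers had -0.19 at 5 FPKM, and amino acid starvation genes -0.067 to 0.181 without 1 library. Of 99 named genes besides ALDH1A1, 66 kept direction and call throughout, 0 turned, and 33 lost the call at least once, 18 of them only where 1 library was left out. Lost calls numbered 29 without knockdown sample 5, 28 without knockdown sample 6, 20 without knockdown sample 1, 29 without control sample 6, 14 without control sample 2 and 5 without control sample 3. No paired analysis was possible because the groups share only the number 6. Absolute depth is unknown, so no counting error can be given.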

Other observations

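The tests of a single control library, of a shared state, of pseudogene copies, of expression level and of transcript length and GC, and all lists in the next paragraph, were chosen after the data were seen. The test of other splits was chosen before.

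Genes on a list of the actin cytoskeleton and SRF targets were mostly higher in the knockdown: 18 of 31 rose and 2 fell, with a median log2 difference of 0.47. The 2 that fell were ACTG1 and ZYX (log2 difference -0.33), and 11 were not called. EGR1 and FOS were placed on the immediate early list instead and fell (log2 differences -2.99 and -1.56). The actin list therefore does not speak for SRF targets as a whole. The list includes ANXA1, already named among the largest rises. ACTB, a cytoplasmic actin, went from a mean of 1080 to 1490 FPKM (log2 difference 0.46, and 0.79 after quantile normalization). The myosin heavy chain MYH9 went from 28.4 to 56.2 FPKM and the integrin ITGA5 from 19.3 to 38.4 FPKM. ACTG1, the other cytoplasmic actin, fell from 2260 to 1630 FPKM. Its log2 difference of -0.47 was -0.04 after quantile normalization, -0.48 after median-centring and -0.46 after correction for transcript length and GC. The list's adjusted p was 1.3e-05 over the 8 lists drawn up after the data were seen, ribosomal proteins included (camera, preset correlation), and 0.16 with an estimated correlation. Heat shock chaperones went the other way, with 11 of 25 falling and 1 rising (median -0.35, and -0.18 after quantile normalization; adjusted p = 0.00028, and 0.28 with an estimated correlation), among them HSPA8, from 309 to 134 FPKM, and HSP90AA1, from 254 to 113 FPKM. Of 22 immediate early genes 10 fell and 2 rose (median -0.26, and -0.13 without control sample 2; adjusted p = 0.025, and 0.18 with an estimated correlation), with FOS going from 3.47 to 0.513 FPKM and the phosphatase DUSP6 from 4.74 to 1.14 FPKM. Of 34 translation factors, EEF1A1 left out, 15 fell and 2 rose (median -0.26, and -0.11 after quantile normalization; adjusted p = 4.4e-05, and 0.12 with an estimated correlation), and genes matched on level had a median of -0.14. Of 31 proteasome genes 13 fell and 0 rose (median -0.19, and -0.11 after quantile normalization; adjusted p = 0.00047, and 0.31 with an estimated correlation), and genes matched on level had a median of -0.08. Cancer-testis antigens (1 of 8 rose and 3 fell, adjusted p = 0.71) and HES, HEY and Notch genes (4 of 16 rose and 4 fell, adjusted p = 0.71) did not pass. The lists were drawn up from these samples, so their directions are not independent evidence.

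Of the 10 splits of the 6 samples into 3 and 3, 1, the real one, called 3952 genes, and the highest of the others called 7. Every other split mixes knockdown and control samples, so any group difference adds to the spread within its groups and lowers its calls. Its calls are therefore no estimate of calls by chance. With 10 splits no share under 0.05 can be reached.

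The lower cholesterol genes are the pattern most tied to the question of the series. Leaving out any 1 library left the list's median at -0.45 or lower, which argues against a single control library. After removal of a per-sample trend on transcript length and GC the median was -0.50 (SE 0.10), with 14 of 24 genes lower. Before that removal it was -0.55. The list's median lay -0.56 (SE 0.11) from genes matched on expression level. By these medians neither trend accounts for the pattern. The SEs of medians here and in the next paragraph were taken across genes as if independent. They do not measure the spread between samples, and are too small where genes move together. A shared state of the cultures, such as density or time since feeding, stays open: the genes moved together between replicates, and with that correlation estimated the unadjusted p was 0.22. An effect of ALDH1A1 loss and a difference between transduced lines stay open too, and neither was tested.

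All 80 ribosomal protein genes had a log2 difference below 0, and 68 were called lower (median -0.43, SE 0.04; camera adjusted p = 9.7e-25 over the 8 lists, and 0.12 with an estimated correlation), taking their share of summed FPKM from 35.6 ± 0.28% in the control to 30.8 ± 0.73% in the knockdown (SD, n = 3). Removal of a length and GC trend left a median of -0.34 (SE 0.04 across genes), with 73 of 80 genes below 0. By these values such a trend is not the whole of it. Whether a trend with expression level accounts for it stays open. The median differed by -0.04 from other genes matched on level (SE 0.13, from matched genes counted once each). Only 25 other genes lay at 1000 FPKM or more, among them the translation factors EEF1G (log2 difference -0.42), EEF2 (-0.47) and the doubtful EEF1A1. The match therefore cannot tell a level trend from a fall shared by translation genes. After quantile normalization the median was -0.05, with 21 lower and 5 higher. That scaling gives every sample the same distribution, so it would remove a fall of the highest genes whatever its cause. The match was poor, at a median of 1740 against 2430 FPKM, and a first match that counted each gene once, at 348 FPKM, gave -0.31. The closer match was chosen after the first was seen, and few genes decide it. Reads moved to pseudogene copies could not be settled, since the 7 tested pseudogenes had a median of 0.15 (SE 0.18).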
